A study of Mus musculus with 11 samples.

How the data were processed

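Bulk RNA-seq was carried out by the submitters on total RNA of epithelial cells isolated from mouse colon; ribosomal RNA was removed enzymatically before library preparation and sequencing was paired-end, per the labels' protocols. The authors deposited 1 table of whole-number gene counts and FPKM values with Ensembl gene identifiers, symbols, coordinates and lengths. The counts are not normalized, per the file headers and the values. STAR, Subread and the genome build mm10 are named, without versions or roles, per the submitters' processing notes; the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited FPKM values equalled the counts scaled by length plus 1 base and by the column total to within 3.64e-12 and were used only for that check. Mitochondrially encoded genes had 0 counts in every library and were not tested.

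Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which kept 19341 of 43346 genes. Libraries were scaled by TMM, and a model with 4 group means over all 11 libraries was fitted with the robust quasi-likelihood method, leaving 7 residual degrees of freedom. The biological coefficient of variation was 51.5%. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 were called. Standard errors of log2 fold changes come from this model. Total counts per library were 20.3 to 50.2 in units of 1e6. Pairs of replicates within a group differed by far more than sampling noise (chi-square per degree of freedom 25.9 to 1043), so no 2 libraries of a group hold the same counts. The replicate numbers are unique to each library and pair none.

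Before the data were examined, the groups, tests, alternatives, named-gene rule and 38 gene lists were fixed. Lists with at least 5 tested members, 36 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the estimated correlation and fry as alternatives. fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. Calls that held with an estimated correlation were matrix remodelling under DSS in both genotypes and xenobiotic metabolism under DSS in knockout mice. Several lists share members, and epithelium also expresses some genes of the other-cell lists. The IL-6 and STAT3 response list holds Il6ra, the gene targeted in the knockout.

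The genes named are Il6ra, Il6st, Il6 and Foxp3 in all cases; per comparison, the 5 largest log2 fold changes in each direction among genes past adjusted p 0.05 with at least 5 CPM on average in the higher group, a symbol and complete separation of the libraries; and of each list described up to 4 members past adjusted p 0.05 with the lowest p, or, where fewer than 2 passed, the 2 members with the lowest p, given as values. Predicted genes and pseudogenes were counted and not named. A few genes that meet these rules are not reported here. Dcn in the description of the libraries is named under the list rule, and Krt8, Epcam and the genes of the closing observations were chosen after their values were seen.

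Alternatives were RLE scaling, a filter at a mean of 1 CPM, no filter, a fold change of at least 2, DESeq2 1.42.0, limma voom with quality weights, fits of only the groups compared, a leukocyte score as covariate and leaving out each library in turn. Offsets that remove each library's trend on GC content and gene length (loess, span 0.5), an epithelial score as covariate and a genotype effect over both treatments were added after the data had been seen. The leukocyte score was the mean log2 CPM of the pan-leukocyte list, and the epithelial score that of the junction and barrier list. Such a covariate takes out much of the contrast of its own list and of lists that vary with it. Changes in those lists under it are no independent check. GC content was taken from the longest reference transcript of each gene on the same assembly, and 99.1% of tested genes had a value. Sex as a covariate was not run: Xist had 0 to 10 counts and Ddx3y 3039 to 10767 in all libraries, so no second sex was present.

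The steps were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For DSS against water in control mice, edgeR on 18872 genes recovered 0 of 67 genes changed 2-fold, 8 of 67 changed 4-fold and 61 of 66 changed 16-fold, with 6 false calls of 75; DESeq2 on 19341 genes made 71 false calls of 180 and limma voom 5 of 70. For DSS against water in knockout mice, edgeR on 18906 genes recovered 0, 4 and 52 at these folds with 1 false call of 57, and DESeq2 made 38 false calls of 136. For knockout against control under DSS, edgeR on 18887 genes recovered 0, 7 and 57 with 0 false calls of 64, and DESeq2 made 34 false calls of 142. For knockout against control on water, edgeR on 18841 genes recovered 0, 3 and 45 with 3 false calls of 51, and DESeq2 made 50 false calls of 135. For the difference of the DSS effect, edgeR on 18885 genes recovered 0, 1 and 21 with 1 false call of 23, and DESeq2 made 32 false calls of 97. In the simulation of knockout against control on water over 19341 genes, camera gave p = 3.3e-13 for a doubled list, 6 of 200 unchanged lists had a p under 0.05, and the offsets brought a GC trend of r = -0.714 to -0.055. Genes were drawn independently and lists at random. The simulation therefore does not test how camera at its preset correlation behaves for lists of correlated genes. Each gene was also drawn with the same spread in all groups. In the data the spread differed: correlations within groups were 0.793 to 0.912 in knockout mice under DSS and 0.959 to 0.979 in control mice on water. Recovery and false calls in the data may therefore differ from those simulated.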

Results

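RNA from colonic epithelial cell preparations of mice was sequenced in 11 libraries. The mice either lacked the IL-6 receptor alpha chain in regulatory T cells (knockout) or carried the Cre control genotype (control), and they drank water or 2% dextran sulfate sodium (DSS), a detergent-like polymer that injures the colonic epithelium. Control mice on water gave 3 libraries (replicates 1, 2 and 3), knockout mice on water 2 (replicates 7 and 8), control mice under DSS 3 (replicates 4, 5 and 6) and knockout mice under DSS 3 (replicates 10, 11 and 12). In units of 1e6, the total gene count was 28.7, 30.4 and 28 in control water replicates 1, 2 and 3, and 20.3 and 50.2 in knockout water replicates 7 and 8. Under DSS it was 27.6, 31.8 and 30.4 in control replicates 4, 5 and 6, and 30.5, 27.4 and 30.3 in knockout replicates 10, 11 and 12. The labels name separate samples without saying how animals relate to them, so the p-values measure the spread between these samples.

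Il6ra, which encodes the deleted receptor chain (ENSMUSG00000027947, chromosome 3, 89869324 to 89913162, mm10), had 751, 863 and 431 counts in control water replicates 1, 2 and 3, and 53 and 87 in knockout water replicates 7 and 8. Under DSS, Il6ra had 535, 2130 and 482 counts in control replicates 4, 5 and 6, and 93, 15 and 411 in knockout replicates 10, 11 and 12. The deletion is directed at regulatory T cells, so Il6ra in epithelial preparations does not check the labels. Il6ra fell in knockout mice on water (log2 fold change -3.48 ± 1.05 (SE), adjusted p = 0.033), and under DSS it was at -2.49 ± 0.84 (adjusted p = 0.227). The call on water was lost with an epithelial score as covariate (-1.32, adjusted p = 0.161) and without knockout water replicate 7 or 8 or control water replicate 1 or 2 (0.157, 0.178, 0.075 and 0.0817). Its log2 fold change was -3.80 and -3.21 without knockout water replicates 7 and 8, and -3.40 and -3.28 without control water replicates 1 and 2. The call on water was kept with DESeq2 (-3.54, adjusted p = 0.000401), limma voom (-3.67, 3.86e-05), only the groups compared (-3.48, 0.000494) and GC and length offsets (-3.30, 0.0361). Under DSS Il6ra was at -3.86 (adjusted p = 0.00688) without knockout DSS replicate 12, -1.58 (0.542) without control DSS replicate 5 and -6.55 (0.00226) with a leukocyte score as covariate. DESeq2 (-2.55, adjusted p = 0.0428) and limma voom (-2.37, 0.00208) called it, and a fit of only the groups compared did not (-2.56, 0.543). The leukocyte score parts the control DSS libraries from all others, so the value with that covariate is an extrapolation. Foxp3, the regulatory T cell transcription factor, had 0 to 20 counts per library. Il6st, the shared signalling subunit of the receptor, averaged 445 ± 92.2 CPM (counts per 1e6 counts; SD, n = 3) in control mice on water and 883 ± 110 (n = 2) in knockout mice on water. Under DSS its counts were 30645, 18505 and 33254 in control replicates 4, 5 and 6. In knockout DSS replicates 10, 11 and 12 they were 23313, 12058 and 23044, so the higher level in knockout mice was not seen under DSS. Il6, the cytokine itself, was at log2 fold changes of 1.01 ± 0.83 (SE) on water and 0.90 ± 0.75 under DSS between genotypes (adjusted p = 0.335 and 0.52).

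Markers of other cells were present in the preparations: Dcn, a fibroblast proteoglycan, averaged 781 CPM in control mice on water (n = 3) and 4030 in knockout mice on water (n = 2). The first principal component held 60.5% of the variance. Within groups the correlation of log2 CPM between libraries was 0.959 to 0.979 in control mice on water, 0.976 in knockout mice on water, 0.935 to 0.976 in control mice under DSS and 0.793 to 0.912 in knockout mice under DSS. Knockout DSS replicate 11 stood apart: Krt8 and Epcam, epithelial structural genes, were at 25.3 and 25.2 CPM there, against 440.3 and 498.7 in replicate 10 and 2100 and 743 in replicate 12. Replicate 12 also differed from its group: its correlation was 0.903 and 0.793 with replicates 10 and 11 and 0.925 to 0.955 with the 6 control libraries, and its neutrophil score was 1.23 against 3.86 and 4.66. The correlation of each library's expression with GC content of genes, across genes, was -0.571 and -0.549 in knockout water replicates 7 and 8 and 0.401 to 0.537 in control water replicates 1, 2 and 3. Counts on processed pseudogenes made up 1.33% and 1.3% in knockout water replicates 7 and 8, 0.65% to 0.77% in control water replicates 1, 2 and 3 and 1.85% in knockout DSS replicate 11. Under DSS the GC correlation did not part the genotypes: it was -0.142, 0.526 and -0.12 in control replicates 4, 5 and 6 and -0.45, -0.258 and 0.33 in knockout replicates 10, 11 and 12.

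**Figure D1:**
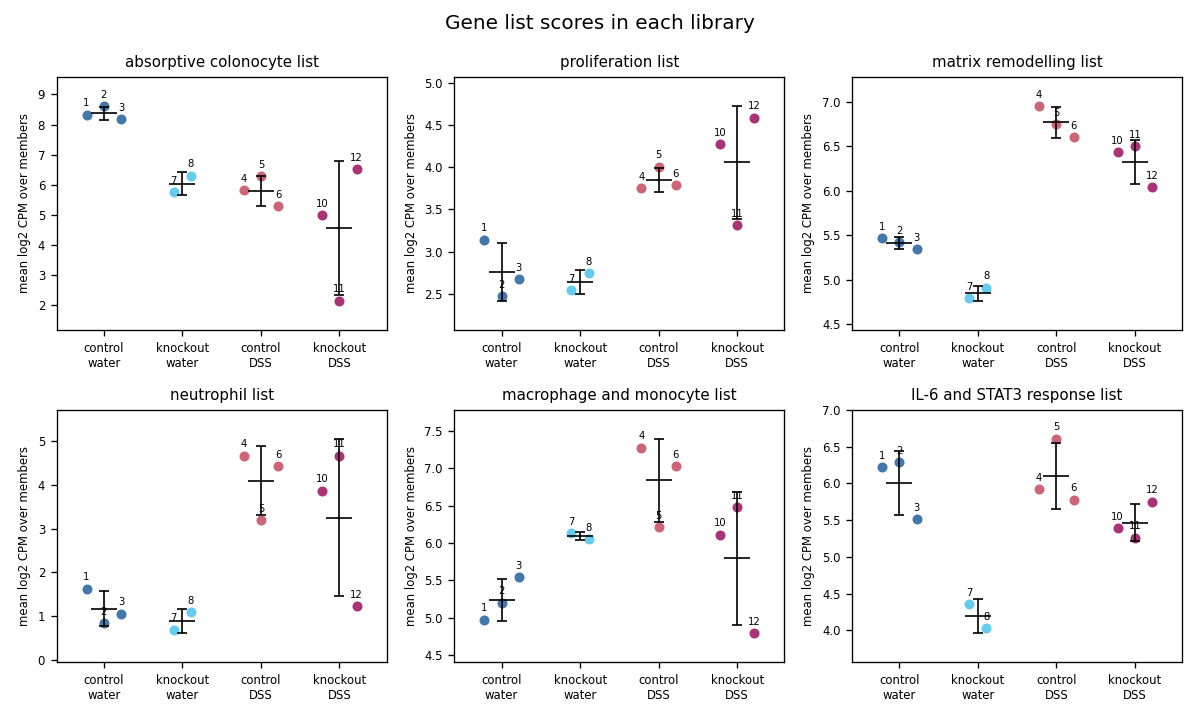
Mean log2 CPM over the members of 6 gene lists in each library (vertical axes), with libraries grouped by genotype and treatment and labelled by replicate number; crossbars are group means and whiskers the SD. The absorptive colonocyte score averaged 8.38 in control mice on water, 6.03 in knockout mice on water, 5.80 in control mice under DSS and 4.57 in knockout mice under DSS, where replicate 11 lay lowest.

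DSS was compared with water in control mice (3 against 3 libraries) to describe the response to epithelial injury. By list tests, genes of absorptive colonocytes were lower under DSS and genes of neutrophils, macrophages and cell division were higher (adjusted p = 0.116 for each of these 4 lists with an estimated correlation). No single gene passed the test over all genes. Car4, a surface carbonic anhydrase, was at log2 fold change -2.77 ± 0.38 (SE), and Aqp8, a water channel, at -4.96 ± 1.22 (adjusted p = 0.143 and 0.157). Hp (haptoglobin) was at 4.31 ± 0.68, Saa3 (an acute-phase protein) at 4.90 ± 1.14 and Il11, a cytokine of the IL-6 family, at 2.95 ± 0.44 (adjusted p = 0.143, 0.157 and 0.143). The IL-6 and STAT3 response list, which holds Hp and Saa3, was not called in this comparison. Its mean log2 CPM averaged 6.01 ± 0.43 (SD, n = 3) on water and 6.1 ± 0.44 (n = 3) under DSS. Ptgs2, the inducible prostaglandin synthase, was at 2.26 ± 0.38 and Ang4, an antimicrobial ribonuclease, at -6.38 ± 1.07 (adjusted p = 0.143 for both).

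Of 19341 genes tested with edgeR, 0 passed an adjusted p of 0.05 and 3000 had an unadjusted p under 0.05 (1709 higher and 1291 lower, where chance gives 967). DESeq2 and limma voom called 1019 and 10377. In 6962 genes (36%) every library of one group lay above every library of the other, where chance gives 10%. Without knockout DSS replicate 11 or 12, which enter through the shared estimate of spread, edgeR called 954 and 865 genes.

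Among the epithelial lists fixed beforehand, the enteroendocrine (median -0.27, adjusted p = 0.261), stem and Wnt target (-0.41, 0.334), regenerative (-0.60, 0.0605) and tuft cell (0.75, 0.0882) lists were not called. The absorptive colonocyte list fell (26 of 26 members below 0, median log2 fold change -2.46, camera adjusted p = 2.11e-15; adjusted p = 0.116 with an estimated correlation). Of its members 0 passed over all genes and 16 adjusted over the list alone. Ion and water transport genes fell (27 of 29 below 0, median -1.68, adjusted p = 2.79e-10; adjusted p = 0.192 with an estimated correlation), and 2 members were lower adjusted over the list alone. Junction and barrier genes fell (23 of 26 below 0, median -1.59, adjusted p = 8.04e-06; adjusted p = 0.287 with an estimated correlation). In the junction list Cldn1, a tight junction claudin, was at 2.03 ± 0.44 and Jup (plakoglobin) at -2.42 ± 0.91, with 1 member higher adjusted over the list alone. Goblet cell genes fell (median -1.10, adjusted p = 0.000785; adjusted p = 0.374 with an estimated correlation). Zg16, a mucus lectin, was at -2.44 ± 0.88, and 0 members passed adjusted over the list alone. Without control water replicate 1 the goblet cell median was -0.61. Cholesterol synthesis (median -1.06), oxidative phosphorylation (-0.74), fatty acid oxidation (-0.71) and xenobiotic metabolism (-1.01) fell too. Of these lists 4, 0, 0 and 7 members were lower adjusted over the list alone. Their camera adjusted p-values were 2.04e-08, 6.21e-08, 0.000749 and 3.71e-07, and with an estimated correlation the adjusted p was 0.116, 0.374, 0.116 and 0.0991. Examples are Fdft1 (squalene synthase) at -1.46 ± 0.40, Cox5a (a cytochrome oxidase subunit) at -1.23 ± 0.32 and Abcb1a (an efflux pump) at -1.77 ± 0.37.

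Genes of infiltrating cells and of cell division rose. The neutrophil list rose (20 of 23 above 0, median 3.12, adjusted p = 1.69e-13; adjusted p = 0.116 with an estimated correlation). Of its members 0 passed over all genes and 18 adjusted over the list alone, among them Mmp9 (gelatinase B) at 2.98 ± 0.52 and Fpr2 (a formyl peptide receptor) at 5.19 ± 1.17. The macrophage and monocyte list rose (19 of 20 above 0, median 1.82, adjusted p = 1.39e-12; adjusted p = 0.116 with an estimated correlation). Cd163, a scavenger receptor, was at 2.23 ± 0.44, and 15 members were higher adjusted over the list alone. All 18 pan-leukocyte genes were above 0 (median 1.46, adjusted p = 1.91e-09; adjusted p = 0.0568 with an estimated correlation), 13 of them passing adjusted over the list alone. All 30 proliferation genes were above 0 (median 0.99, adjusted p = 2.79e-10; adjusted p = 0.116 with an estimated correlation). Ccna2 (cyclin A2) was at 2.21 ± 0.48, and 9 members were higher adjusted over the list alone. Matrix remodelling genes rose and the call held with an estimated correlation (median 1.25, adjusted p = 1.33e-07; adjusted p = 0.0172 with an estimated correlation). Lox, which crosslinks collagen, was at 2.27 ± 0.46, and 14 of 24 members were higher adjusted over the list alone. Inflammatory cytokine and chemokine genes rose (30 of 38 above 0, median 1.29, adjusted p = 1.85e-07; adjusted p = 0.116 with an estimated correlation; 11 adjusted over the list alone). With a leukocyte score as covariate 4 of the 25 list calls of this comparison were kept, 10 were lost and 11 turned. The macrophage list was then called lower (median -0.745, adjusted p = 0.0156), and the neutrophil (-1.61, 0.133), cytokine (-0.55, 0.326) and pan-leukocyte (0.034, 0.741) lists were not called. The absorptive colonocyte call was lost as well (median 0.418, adjusted p = 0.777). The leukocyte score was 5.46 to 6.18 in the control DSS libraries and 4.2 to 4.88 in all others. This covariate is therefore hardly separable from the group, and the adjusted values are extrapolations. It is also the mean of the pan-leukocyte list, so the loss of that call was fixed in advance.

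The T cell (median 0.94), regulatory T cell (1.01), B cell (0.57), plasma cell (0.91), fibroblast and smooth muscle (0.80), mast cell (0.86) and red blood cell (1.82) lists rose in control mice under DSS. Their camera adjusted p-values were 3.6e-05, 0.00261, 0.0401, 0.0057, 0.000655, 0.00481 and 0.00944. Their adjusted p was 0.116, 0.116, 0.423, 0.374, 0.0811, 0.116 and 0.374 with an estimated correlation. Respectively 0, 3, 0, 0, 0, 2 and 0 members were higher adjusted over the list alone. Over all libraries the 13 regulatory T cell genes had 76230 counts and the 24 T cell genes 30333, while Foxp3 had 0 to 20 per library. Other cells may thus supply much of the regulatory T cell list, and its rise does not measure the number of regulatory T cells. The antimicrobial (median -1.05), type I interferon (-0.29), small intestine and Paneth cell (-1.92) and dissociation and immediate early (-0.86) lists fell, with adjusted p-values of 0.00694, 0.00446, 0.000118 and 0.00213. With an estimated correlation the adjusted p was 0.423, 0.476, 0.116 and 0.374. Adjusted over the list alone, 4 antimicrobial genes were lower and 2 higher, and 2, 3 and 0 members of the other lists were lower. The type I interferon call was lost without control water replicate 3 (adjusted p = 0.282) or control DSS replicate 5 (0.497). The B cell call was lost without control water replicate 2 (0.394), control DSS replicate 5 (0.105) or knockout DSS replicate 12 (0.0564). The mast cell call was lost without control DSS replicate 4 (adjusted p = 0.0637), the red blood cell call without control DSS replicate 6 (0.0812) and the antimicrobial call without knockout DSS replicate 12 (0.052). Without control water replicate 2 the type I interferon, mast cell and immediate early medians were -0.49, 1.69 and -0.495, and without replicate 3 the B cell median was 0.97. Without control DSS replicate 4 or 6 the type I interferon median was -0.45 and -0.47, and without replicate 5 the immediate early median was -1.44.

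The same treatment was compared in knockout mice (3 against 2 libraries). Nxpe4, a colon-expressed gene of the neurexophilin family (ENSMUSG00000044229, chromosome 9, 48362041 to 48400025), fell from 72.4 ± 27.6 CPM (SD, n = 2) on water to 2.85 ± 0.887 (n = 3) under DSS. Its log2 fold change was -4.67 ± 0.51 (SE; adjusted p = 0.0318). It was the 1 gene of 19341 that passed with edgeR, against 571 with DESeq2 and 1684 with limma voom. Saa3 was at 7.59 ± 1.55, Hp at 4.94 ± 0.84 and Birc5 (survivin, a mitotic gene) at 2.78 ± 0.45 (adjusted p = 0.313, 0.296 and 0.296). Chac1, a target of the integrated stress response, was at 3.19 ± 0.52 and Ifit1, an interferon-induced gene, at -3.25 ± 0.74 (adjusted p = 0.296 and 0.328).

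An unadjusted p under 0.05 was found for 2631 genes (2015 higher and 616 lower), and 5016 genes (25.9%) separated the groups completely, where chance gives 20%. The median log2 fold change over all genes was 0.36 in this comparison, and with GC and length trends taken out it shifted by -0.19. The Nxpe4 call was lost without knockout water replicate 8 (log2 fold change -5.01, adjusted p = 0.0864), knockout water replicate 7 (-4.22, adjusted p = 0.176) or control water replicate 1, 2 or 3 (adjusted p = 0.114, 0.114 and 0.1). It was also lost without control DSS replicate 4 or 6 (0.0933 and 0.0771) or knockout DSS replicate 10 or 11 (0.204 and 0.0829), and in a fit of only these 5 libraries (-4.79, adjusted p = 0.855). With knockout DSS replicate 12 left out, 38 genes passed.

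In knockout mice, matrix remodelling genes rose (23 of 24 above 0, median 1.61, adjusted p = 1.29e-08; adjusted p = 0.0094 with an estimated correlation), with 0 over all genes and 14 adjusted over the list alone. Mmp9 was at 3.77 ± 0.69. Xenobiotic metabolism genes fell (30 of 37 below 0, median -1.02, adjusted p = 2.58e-12; adjusted p = 0.0315 with an estimated correlation). Abcb1a was at -1.54 ± 0.40 and Ces1g, a carboxylesterase, at 3.72 ± 0.92, and 5 members were lower and 2 higher adjusted over the list alone. Proliferation genes rose (29 of 30 above 0, median 1.83, adjusted p = 6.51e-13; adjusted p = 0.114 with an estimated correlation). Ube2c, a mitotic ubiquitin-conjugating enzyme, was at 2.96 ± 0.52, and 15 members were higher adjusted over the list alone. All 23 neutrophil genes were above 0 (median 3.77, adjusted p = 1.41e-08; adjusted p = 0.247 with an estimated correlation). Csf3r, the G-CSF receptor, was at 2.17 ± 0.57, and 14 members were higher adjusted over the list alone. IL-6 and STAT3 response genes rose (25 of 28 above 0, median 1.55, adjusted p = 1.58e-05; adjusted p = 0.204 with an estimated correlation; 4 adjusted over the list alone). Inflammatory cytokine genes (median 1.498, adjusted p = 0.000392) and protein folding and stress response genes (median 0.56, adjusted p = 0.000283) rose as well. The adjusted p was 0.396 and 0.204 with an estimated correlation, and 8 and 3 members were higher adjusted over the list alone. With knockout DSS replicate 12 left out, the xenobiotic median was -1.63 and the STAT3 median 0.79, and without replicate 11 the neutrophil median was 2.27.

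The regulatory T cell (median 0.91), red blood cell (1.97) and non-polyadenylated histone (1.21) lists rose in knockout mice under DSS (adjusted p = 0.0153, 0.0464 and 0.047). For these the adjusted p was 0.247, 0.665 and 0.396 with an estimated correlation. Here too the rise of the regulatory T cell list does not measure the number of regulatory T cells, as most of its counts are not from Foxp3. The absorptive colonocyte (median -0.62), type I interferon (-0.63), interferon gamma and antigen presentation (-0.43), fatty acid oxidation (-0.17) and small intestine (-1.26) lists fell (adjusted p = 8.81e-07, 4.04e-08, 0.0044, 0.00217 and 1.05e-05). For these 5 lists the adjusted p was 0.447, 0.393, 0.606, 0.247 and 0.114 with an estimated correlation. Adjusted over the list alone, 1 type I interferon gene and 3 small intestine genes were lower, 1 small intestine gene was higher, and 0 members of the other 6 of these 8 lists passed. Junction genes and ion transport genes were called lower relative to other genes (adjusted p = 0.0304 and 0.0013; adjusted p = 0.711 and 0.665 with an estimated correlation), with 0 members adjusted over the list alone. The junction median and mean were above 0 (0.185 and 0.27), as was the ion transport median (0.04), while the ion transport mean was -0.08. Without knockout DSS replicate 11 the absorptive colonocyte, ion transport, cytokine, regulatory T cell, red blood cell and histone calls were lost (adjusted p = 0.065, 0.473, 0.174, 0.111, 0.507 and 0.073). The junction list turned upward without that library (median 0.38, adjusted p = 0.729). The interferon gamma call was lost without knockout water replicate 7 or knockout DSS replicate 12 (adjusted p = 0.0953 and 0.204), and the regulatory T cell call without knockout DSS replicate 10 (0.0541). The junction call was lost without knockout water replicate 8 (0.181), and the red blood cell call without knockout water replicate 8 or knockout DSS replicate 12 (0.105 and 0.204). The histone call was lost without knockout water replicate 8, knockout DSS replicate 12 or control DSS replicate 5 (0.103, 0.374 and 0.0586). With knockout DSS replicate 12 left out, the absorptive colonocyte, junction, ion transport, fatty acid oxidation and small intestine medians were -1.41, -1.09, -1.48, -0.52 and -2.18. Without knockout water replicate 7 the ion transport, type I interferon and small intestine medians were -0.08, -0.27 and -0.25, and without replicate 8 the absorptive colonocyte and ion transport medians were -0.18 and 0.16. When knockout DSS replicate 10 was left out, the junction and ion transport medians were 0.38 and 0.14, without replicate 11 the type I and gamma interferon medians were -0.96 and -0.87, and without control water replicate 3 the ion transport median was -0.02.

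Knockout was compared with control under DSS (3 against 3 libraries), the setting in which the role of the receptor in regulatory T cells during injury is addressed. Nlrp3, the sensor of an inflammasome (ENSMUSG00000032691, chromosome 11, 59541568 to 59566956), fell from 327 ± 78 CPM (SD, n = 3) in control to 18.9 ± 9.85 (n = 3) in knockout mice (log2 fold change -4.11 ± 0.44 (SE), adjusted p = 0.0292). Nxpe4 fell from 48.3 ± 21 to 2.85 ± 0.887 CPM (-4.08 ± 0.48, adjusted p = 0.0311), and Mptx1, a mucosal pentraxin (ENSMUSG00000026531, chromosome 1, 174330518 to 174332873), from 45.7 ± 32.4 to 0.151 ± 0.113 CPM (-8.13 ± 1.09, adjusted p = 0.0413). Slc15a3, a lysosomal peptide and histidine transporter (ENSMUSG00000024737, chromosome 19, 10839727 to 10859362), fell from 138 ± 13.5 to 33.6 ± 4.96 CPM (-2.04 ± 0.27, adjusted p = 0.0413). On water the control and knockout means were 116 and 21.4 CPM for Nlrp3, 410 and 50.6 for Mptx1 and 57.5 and 21.7 for Slc15a3. For Nxpe4 they were 55.7 and 72.4. The means of Nlrp3, Mptx1 and Slc15a3 were thus lower in knockout mice without injury too, and that of Nxpe4 was not. Il23a, a cytokine subunit, was at -3.06 ± 0.52, Laptm5, a leukocyte lysosomal protein, at -1.95 ± 0.32 and Cd4, the T helper coreceptor, at -2.35 ± 0.40 (adjusted p = 0.078 for each).

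With edgeR, 6 of 19341 genes passed, all lower in knockout mice; the other 2 are an antisense transcript and an immunoglobulin variable segment. DESeq2 called 509 and limma voom 8302. An unadjusted p under 0.05 was found for 3565 genes (2595 higher and 970 lower), and 2482 genes (12.8%) separated the groups completely, where chance gives 10%. The count was 0 without any 1 control water library or control DSS replicate 4 or 6, and 1 without knockout DSS replicate 10. It was 2 without control DSS replicate 5, 4 without knockout DSS replicate 11 or knockout water replicate 7 or 8, and 6954 without knockout DSS replicate 12. A fit of only these 6 libraries called 0 genes and RLE scaling 3, with Mptx1 and Slc15a3 at an adjusted p of 0.053. The Nlrp3 call was lost without control water replicate 1, 2 or 3 (adjusted p = 0.0922, 0.0752 and 0.0718) or control DSS replicate 4 or 6 (0.0796 and 0.0673). The Nxpe4 call was lost without the same libraries (0.0922, 0.0752, 0.0718, 0.117 and 0.107) or knockout DSS replicate 10 or 11 (0.13 and 0.0564). For Mptx1 the same held (0.0922, 0.105, 0.0718, 0.0796, 0.137, 0.168 and 0.105), and also without control DSS replicate 5 (0.0715). The Slc15a3 call was lost without any library except knockout DSS replicates 11 and 12 (adjusted p = 0.0935 to 0.265). Slc15a3 was at -1.17 (adjusted p = 0.286) with GC and length trends taken out.

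**Figure D2:**
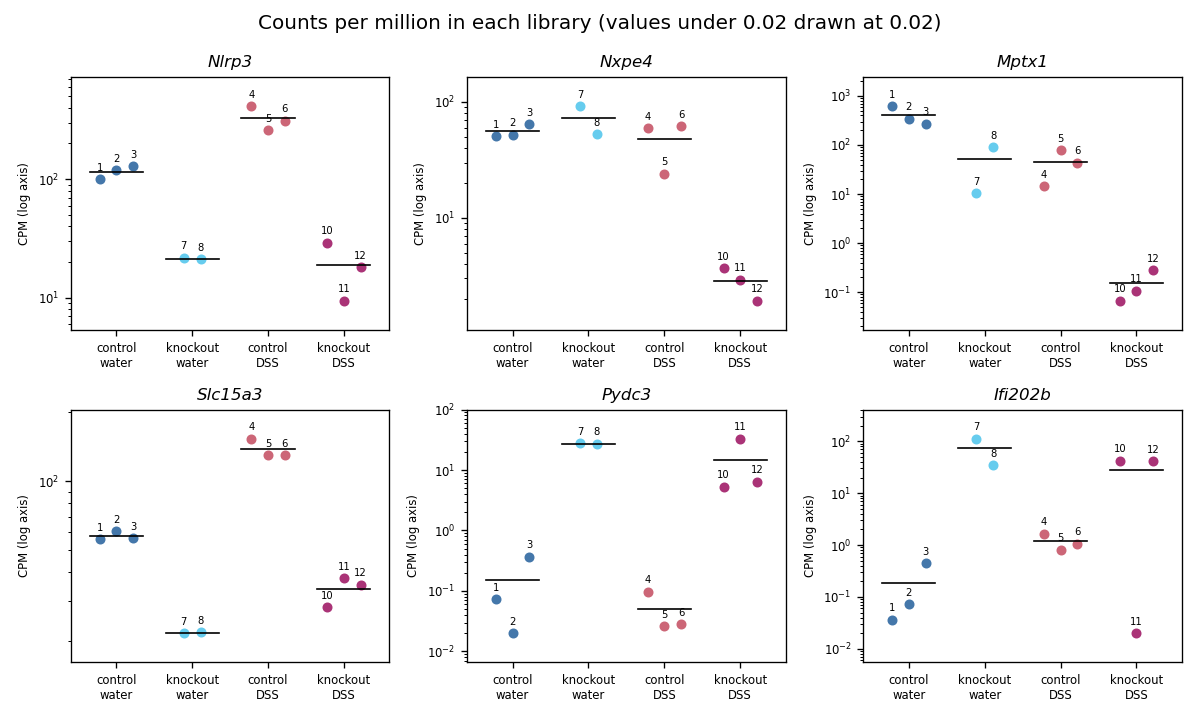
CPM of 6 genes in each library on log axes, with libraries grouped by genotype and treatment and labelled by replicate number; horizontal lines are group means, and values under 0.02 CPM are drawn at 0.02. Nlrp3 lay at 18.9 CPM on average in knockout mice under DSS against 327 in control mice, and Pydc3 reached at most 0.368 CPM in any control library against at least 5.31 in any knockout library.

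Oxidative phosphorylation genes rose in knockout mice under DSS (37 of 39 above 0, median 1.15, adjusted p = 1.26e-10; adjusted p = 0.563 with an estimated correlation), with 0 over all genes and 27 adjusted over the list alone. Ndufa4, a respiratory chain subunit, was at 2.28 ± 0.72. Red blood cell genes rose (8 of 8 above 0, median 3.21, adjusted p = 2.25e-07; adjusted p = 0.442 with an estimated correlation). The globin Hbb-bt was at 4.13 ± 0.81, and 6 members were higher adjusted over the list alone. Pan-leukocyte genes fell (15 of 18 below 0, median -1.24, adjusted p = 5.46e-08; adjusted p = 0.168 with an estimated correlation). Itgb2, the leukocyte beta integrin, was at -2.22 ± 0.38, and 6 members were lower adjusted over the list alone. Macrophage and monocyte genes fell (15 of 20 below 0, median -1.24, adjusted p = 2.63e-06; adjusted p = 0.546 with an estimated correlation). C1qb, a complement subunit, was at -1.76 ± 0.30 and Csf1r, the M-CSF receptor, at -2.67 ± 0.53, and 8 members were lower adjusted over the list alone. Inflammatory cytokine genes fell (median -0.63, adjusted p = 0.000155; adjusted p = 0.546 with an estimated correlation). Osm (oncostatin M) was at -2.13 ± 0.38, and 8 members were lower and 1 higher adjusted over the list alone. T cell genes (median -0.43, adjusted p = 0.0136) and mast cell genes (median -1.80, adjusted p = 0.00115) fell. The adjusted p was 0.563 and 0.442 with an estimated correlation, and 3 and 2 members were lower adjusted over the list alone. Without knockout DSS replicate 12 the macrophage (adjusted p = 0.187), cytokine (0.268), T cell (0.605) and mast cell (0.214) calls were lost, and the T cell call was also lost without control DSS replicate 4 (0.0596). With knockout DSS replicate 11 left out, the oxidative phosphorylation median was 0.52 (adjusted p = 1.16e-07) and the T cell median -0.745. The oxidative phosphorylation score was 7.68, 8.63 and 6.86 in knockout DSS replicates 10, 11 and 12 and 6.84, 6.74 and 6.92 in control DSS replicates 4, 5 and 6. With a leukocyte score as covariate the macrophage list was called higher (median 0.97, adjusted p = 0.0404), and 7 of the 18 list calls were kept, 4 lost and 7 turned. As the score parts the control DSS libraries from all others, these values are extrapolations too.

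The goblet cell (median -0.92), stem and Wnt target (-0.78), ion transport (-0.60), junction (-0.49) and absorptive colonocyte (-0.32) lists fell (adjusted p = 0.00619, 0.0136, 0.0338, 0.0338 and 0.0481). With an estimated correlation their adjusted p was 0.643, 0.643, 0.663, 0.663 and 0.663, and 0 members passed adjusted over the list alone. Creb3l1, a secretory pathway regulator of goblet cells, was at -1.97 ± 0.87 and Cyp2c55, a colonic cytochrome P450, at -3.13 ± 1.24. Without knockout DSS replicate 11, in which epithelial genes were lowest, the goblet (adjusted p = 0.1) and ion transport (0.993) calls were lost. The absorptive colonocyte median was then 0.058 and the junction median 0.02 (adjusted p = 0.427 and 0.981). The goblet call was also lost without knockout DSS replicate 12 (0.113), the absorptive call without control DSS replicate 4 or 5 (0.102 and 0.164). The stem, junction and ion transport calls were lost without control DSS replicate 5 (0.147, 0.118 and 0.198). Without knockout DSS replicate 12 the absorptive colonocyte, stem, junction and ion transport medians were -1.43, -1.68, -1.25 and -1.59, and without replicate 10 they were -0.19, -0.47, -0.31 and -0.37. The absorptive colonocyte median was -0.496 without control DSS replicate 6, and the goblet cell median -0.435 without replicate 5.

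The IL-6 and STAT3 response list fell (21 of 28 below 0, median -0.65, adjusted p = 0.0481; adjusted p = 0.643 with an estimated correlation). Pim1, a STAT3 target kinase, was at -1.65 ± 0.52 and Timp1, a metalloproteinase inhibitor, at 2.78 ± 0.84, and 0 members passed adjusted over the list alone. Il6ra, a member of this list, was among those below 0. Immediate early genes fell (25 of 29 below 0, median -0.53, adjusted p = 0.0422; adjusted p = 0.663 with an estimated correlation; 0 adjusted over the list alone). Plasma cell genes were called lower (mean -0.19, adjusted p = 0.042; adjusted p = 0.643 with an estimated correlation; 1 lower adjusted over the list alone) although their median was 0.34. Proliferation (median 0.53), cholesterol synthesis (0.47) and non-polyadenylated histone (0.75) genes rose, with adjusted p-values of 0.0154, 0.0302 and 0.0489. With an estimated correlation the adjusted p was 0.643, 0.643 and 0.55, and 1, 0 and 0 members were higher adjusted over the list alone. With knockout DSS replicate 12 left out, the STAT3, plasma cell, proliferation, cholesterol and histone calls were lost (adjusted p = 0.368, 0.97, 0.483, 0.187 and 0.649). Without replicate 10 the STAT3, proliferation, cholesterol and immediate early calls were lost (0.056, 0.056, 0.163 and 0.122). Immediate early genes were also not called without knockout DSS replicate 11 (0.123) or control DSS replicate 5 (0.302), and STAT3 genes without control DSS replicate 5 (0.198). Cholesterol, plasma cell and histone genes were not called without control DSS replicate 4 (0.0929, 0.102 and 0.102) or 6 (0.12, 0.113 and 0.115). The plasma cell median was 0.54 without knockout DSS replicate 10 and -1.20 without replicate 11, and the immediate early median -0.97 without replicate 12.

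Knockout was compared with control on water (2 against 3 libraries), which asks what the genotype does without injury. Many epithelial genes fell in knockout mice. Slc9a3, the apical sodium-proton exchanger, fell from 221 to 1.28 CPM (log2 fold change -7.43 ± 2.20 (SE), adjusted p = 0.0313). Ang4 fell from 45.2 to 0.178 CPM (-8.30 ± 1.46, adjusted p = 0.024) and Fcgbp, a mucus protein, from 459 to 4.60 CPM (-6.63 ± 1.86, adjusted p = 0.0275). Fer1l4, of the ferlin family, fell by 6.95 ± 2.02 and Aim1l by 6.42 ± 1.69 on the log2 scale (adjusted p = 0.0299 and 0.0247). Ifi202b and Pydc3, interferon-inducible genes of one family (ENSMUSG00000026535 and ENSMUSG00000066677, chromosome 1, 173962568 to 173982744 and 173673675 to 173698392), rose by 8.62 ± 1.88 and 7.51 ± 1.18 (adjusted p = 0.024 for both). Cntnap5a, a cell adhesion gene, rose by 4.88 ± 0.70 and Cpa6, a carboxypeptidase, by 4.504 ± 0.77 (adjusted p = 0.024 for both).

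With edgeR 5829 of 19341 genes passed (30.1%), 1896 higher and 3933 lower. DESeq2 called 7751 and limma voom 13732. Complete separation held for 14991 genes (77.5%), where chance gives 20%. The fold changes followed GC content (across 9748 protein-coding genes, r = -0.578; genes are not independent replicates). The median was 0.94 in the 10% of genes with the lowest GC content and -2.66 in the 10% with the highest. With GC and length trends taken out 4010 genes passed, 1838 higher and 2172 lower (45.8% higher against 32.5%), of which 2720 were among the 5829. With an epithelial score as covariate 1219 passed, 894 of them among the 5829, and the Slc9a3, Fcgbp, Fer1l4, Aim1l and Il6ra calls were lost (adjusted p = 0.378, 0.0876, 0.417, 0.145 and 0.161). That score, from junction genes, averaged 5.75 in knockout and 7.81 in control mice on water, so it takes out part of the genotype contrast itself. The count was 0 without knockout water replicate 7 or 8 or control water replicate 1 or 2. It was 9723 without knockout DSS replicate 11, 9406 without knockout DSS replicate 12 and 9637 with a leukocyte score as covariate.

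**Figure D3:**
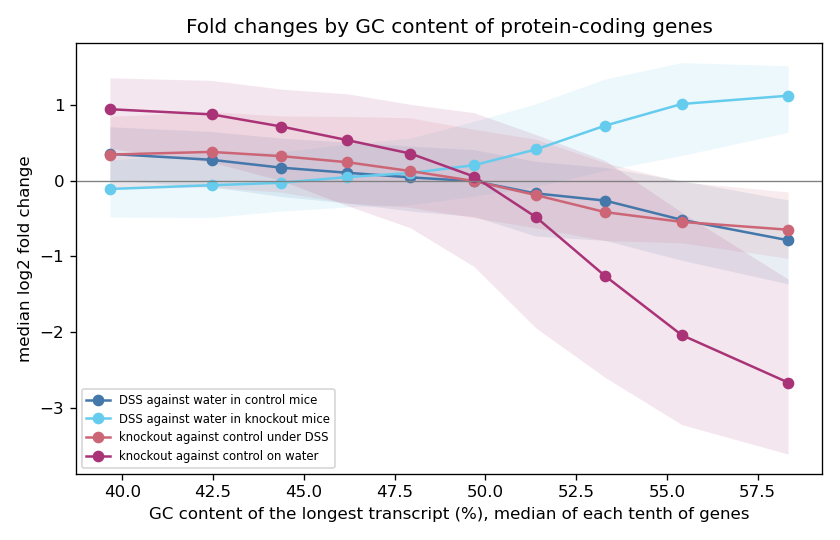
Median log2 fold change (vertical axis) of protein-coding genes, binned into 10 equal groups by GC content of the longest transcript (horizontal axis, percent) for 4 comparisons; bands span the middle 50% of genes. Knockout against control on water ran from 0.942 in the lowest group to -2.66 in the highest, and DSS against water in knockout mice from -0.11 to 1.12.

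Of the epithelial lists on water, 4 fell, while the junction (median -1.63, adjusted p = 0.0549), regenerative (-0.61, 0.32), enteroendocrine (-0.79, 0.658) and tuft cell (median 0.26, mean -0.27, 0.72) lists were not called. In the absorptive colonocyte list 8 of 26 fell (median -2.04, adjusted p = 0.00682; adjusted p = 0.904 with an estimated correlation), and 8 adjusted over the list alone. Car4 was at -1.85 ± 0.43, Scnn1b, a sodium channel subunit, at -4.48 ± 1.30 and Fabp2, a fatty acid binding protein, at -3.19 ± 0.94. Among ion and water transport genes 10 of 29 fell (median -1.86, adjusted p = 0.00713; adjusted p = 0.904 with an estimated correlation), and 12 adjusted over the list alone. The chloride channel Clcn2 was at -5.21 ± 1.53 and the potassium channel Kcnq1 at -3.11 ± 0.82. Among goblet cell genes 10 of 24 fell and 1 rose (median -2.56, adjusted p = 0.0261; adjusted p = 0.904 with an estimated correlation), with 12 lower and 1 higher adjusted over the list alone. Muc2, the main colonic mucin, fell by 4.21 ± 0.99, Spdef, a goblet cell transcription factor, by 5.41 ± 1.38 and Retnlb by 4.08 ± 0.67, while Clca1, a mucus-processing protease, rose by 1.53 ± 0.35. Stem and Wnt target genes fell in 10 of 22 (median -2.15, adjusted p = 0.00713; adjusted p = 0.904 with an estimated correlation), with 12 lower and 1 higher adjusted over the list alone. Ephb2 and Ephb3, receptors that position crypt cells, were at -6.06 ± 1.43 and -3.99 ± 0.91 and Myc at -3.85 ± 0.96. The goblet cell call was lost without knockout water replicate 7 (adjusted p = 0.106), control water replicate 1 (0.0543) or knockout DSS replicate 12 (0.0699). With GC and length trends taken out, Clca1 was at 0.90, Ephb3 at -1.40, Kcnq1 at -0.88 and Clcn2 at -1.86 (adjusted p = 0.0598, 0.0516, 0.119 and 0.107). With an epithelial score as covariate the calls of Scnn1b, Fabp2, Muc2, Spdef, Ephb3, Myc, Kcnq1 and Clcn2 were lost (adjusted p = 0.177, 0.167, 0.0574, 0.0792, 0.0537, 0.0586, 0.0708 and 0.0694).

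The IL-6 and STAT3 response list fell on water, with 16 of 28 members lower over all genes (median -2.37, adjusted p = 0.00458; adjusted p = 0.904 with an estimated correlation), and 16 lower and 2 higher adjusted over the list alone. Il6ra, the targeted gene, is a member of this list and among the 16 lower ones. Stat3 itself fell from 491 to 51 CPM (-3.27 ± 0.75), Pim1 from 203 to 24 (-3.08 ± 0.65) and Reg3g, an antimicrobial lectin, from 242 to 31.7 (-2.93 ± 0.67). Bcl3, an NF-kappa-B cofactor, fell by 3.59 ± 0.81 and was at -0.90 (adjusted p = 0.0636) with GC and length trends taken out. Immediate early genes, which respond to cell isolation, fell in 17 of 29 and rose in 1 (median -2.55, adjusted p = 0.00458; adjusted p = 0.904 with an estimated correlation), with 18 lower and 1 higher adjusted over the list alone. Fos was at -3.47 ± 0.91 and Zfp36 at -3.66 ± 0.84. Red blood cell genes rose in 6 of 8 (median 3.05, adjusted p = 0.00458; adjusted p = 0.904 with an estimated correlation), and 6 adjusted over the list alone. The globins Hba-a2 and Hbb-bs were at 4.18 ± 0.93 and 3.05 ± 0.88, and Hbb-bs was at 2.32 (adjusted p = 0.0648) with GC and length trends taken out. With an epithelial score as covariate the calls of Bcl3, Reg3g, Zfp36, Fos, Hba-a2 and Hbb-bs were lost (adjusted p = 0.0538, 0.071, 0.0509, 0.0637, 0.059 and 0.137).

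The macrophage, fibroblast and endothelial lists were not called on water, and their members went both ways. Among macrophage and monocyte genes 6 of 20 rose and 3 fell (median 1.61, adjusted p = 0.0599), and the same numbers adjusted over the list alone. Mrc1, the mannose receptor, rose by 1.93 ± 0.44, and Csf1r fell by 2.69 ± 0.63. Among fibroblast and smooth muscle genes 8 of 22 rose and 6 fell (median -0.22, mean 0.03, test upward, adjusted p = 0.517), with 9 higher and 8 lower adjusted over the list alone. The matrix proteins Postn, Dpt and Dcn rose by 1.995 ± 0.38, 2.87 ± 0.63 and 2.37 ± 0.53. Endothelial genes rose in 5 of 20 and fell in 5 (median -0.12, mean -0.21, test upward, adjusted p = 0.816), with 5 higher and 6 lower adjusted over the list alone. Pecam1, an endothelial adhesion molecule, rose by 2.10 ± 0.50 and Robo4, a guidance receptor, fell by 3.72. With GC and length trends taken out, Csf1r was at -0.92 and Dcn at 0.78 (adjusted p = 0.0962 and 0.107). With an epithelial score as covariate the calls of Mrc1, Dpt, Dcn, Pecam1 and Robo4 were lost (adjusted p = 0.0574, 0.0521, 0.0611, 0.0775 and 0.0577).

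The difference of the DSS effect between genotypes was tested in all 11 libraries. With edgeR 0 of 19341 genes passed (3431 with an unadjusted p under 0.05, lowest adjusted p = 0.263). DESeq2 called 735 and limma voom 6724, and without knockout DSS replicate 11 edgeR called 2. The macrophage and monocyte list was called higher under DSS in control mice and not called in knockout mice. The difference, knockout minus control, had a median of -2.002 (18 of 20 below 0, adjusted p = 4.19e-10; adjusted p = 0.483 with an estimated correlation). Cd163 was at -2.99 ± 0.64 (SE) and Mrc1 at -2.82 ± 0.60, and 6 members were lower adjusted over the list alone. Pan-leukocyte genes differed the same way (median -0.72, adjusted p = 0.000319; adjusted p = 0.483 with an estimated correlation). Ptprc (CD45) was at -2.60 ± 0.69, and 6 members were lower adjusted over the list alone. Across genes, the DSS effects in the 2 genotypes had r = 0.004 and rho = -0.124, with the same sign in 47.3% of 19341 genes. The r was -0.206 without knockout DSS replicate 11 and 0.316 without replicate 12. The 2 DSS effects followed GC content in opposite directions (r = -0.386 in control and 0.452 in knockout mice). With GC and length trends taken out, the correlation of the DSS effects was 0.13. A low correlation across genes does not show unrelated responses: matrix remodelling, neutrophil, proliferation and xenobiotic lists were called in the same direction in both genotypes.

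Absorptive colonocyte, ion transport, STAT3 and immediate early genes differed in the other direction, while the goblet cell (median 1.53, adjusted p = 0.14), junction (1.39, 0.168), stem (1.30, 0.0709) and tuft cell (-0.88, 0.061) lists were not called. The IL-6 and STAT3 response list had a median difference of 1.70 (24 of 28 above 0, adjusted p = 0.00832; adjusted p = 0.483 with an estimated correlation). The immediate early list was at 1.64 (adjusted p = 0.00832; adjusted p = 0.704 with an estimated correlation). The absorptive colonocyte list was at 1.65 (adjusted p = 0.0272; adjusted p = 0.862 with an estimated correlation) and the ion transport list 1.49 (adjusted p = 0.043; adjusted p = 0.862 with an estimated correlation). Adjusted over the list alone, 0, 0, 1 and 1 of their members were higher. Car4 was at 2.67 ± 0.55 and Slc9a3 at 7.78 ± 2.45 (adjusted p = 0.263 for both). Cholesterol synthesis (median 0.75), oxidative phosphorylation (0.88) and non-polyadenylated histone (1.48) lists were higher (adjusted p = 0.00378, 0.023 and 0.0117), and T cell (-0.41) and plasma cell (-0.41) lists lower (adjusted p = 0.0117 for both). With an estimated correlation their adjusted p was 0.483, 0.862, 0.483, 0.483 and 0.657, and 0, 0, 0, 0 and 1 members passed adjusted over the list alone. The median over all genes was 0.28 and shifted by -0.16 with GC and length trends taken out. The difference followed GC content about as strongly as the genotype contrast on water did (across 9748 protein-coding genes, r = 0.568 against -0.578). With genes binned by GC content, its median was -0.426 in the lowest bin and 1.966 in the highest. With these trends taken out, 1 of the 11 list calls was lost.

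Of the 11 list calls, 6 were lost when single libraries were left out; the macrophage, pan-leukocyte, STAT3, immediate early and histone calls were not. With a leukocyte score as covariate 1 of the 11 was kept, 5 were lost and 5 turned, and ion transport genes were called lower (median -1.385, adjusted p = 0.00174). Since that score parts the control DSS libraries from all others, these values are extrapolations as well. The absorptive colonocyte call was lost without knockout water replicate 7 (adjusted p = 0.107), knockout DSS replicate 10 (0.141) or 12 (0.893), or control DSS replicate 6 (0.0562). The ion transport call was lost without the same 4 libraries (0.0977, 0.141, 0.836 and 0.0581) or control DSS replicate 4 (0.051). The oxidative phosphorylation call was lost without knockout water replicate 7 (0.117), control water replicate 3 (0.106), knockout DSS replicate 10 (0.0719) or 11 (0.794), or control DSS replicate 5 (0.138). The cholesterol call was lost without knockout DSS replicate 10 (0.0638). The T cell call was lost without control water replicate 3 (0.0555) or knockout DSS replicate 12 (0.0519), and the plasma cell call without knockout DSS replicate 12 (0.154). When knockout DSS replicate 11 was left out, the T cell, plasma cell and pan-leukocyte medians were -1.09, -1.69 and -1.57, and without control water replicate 1 or 2 the T cell medians were -0.63 and -0.63 and the plasma cell medians -0.03 and -0.91. The T cell median was -0.84 without knockout water replicate 8, and the plasma cell median -0.07 without knockout DSS replicate 10 and -0.245 without control DSS replicate 6. The immediate early median was 0.92 without knockout DSS replicate 12, and without control DSS replicate 5 it was 2.59 and the ion transport median 2.37.

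Scores of 14 lists of other cells or tissues, as mean log2 CPM per library, were compared by exact two-sided permutation tests, for which 0.1 is the smallest p these group sizes allow. The neutrophil score was 1.18 ± 0.40 (SD, n = 3) in control mice on water and 4.09 ± 0.79 (n = 3) under DSS (exact p = 0.1, adjusted 0.156). In knockout mice it was 0.89 ± 0.28 (n = 2) and 3.25 ± 1.80 (n = 3) (exact p = 0.2, adjusted 0.7). The red blood cell score was 0.47 ± 0.66 in control and 3.06 ± 0.14 in knockout mice on water (exact p = 0.1, adjusted 0.28). The macrophage score was 6.84 ± 0.56 in control and 5.79 ± 0.88 in knockout mice under DSS (n = 3 and 3, exact p = 0.2, adjusted 0.4).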

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

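The test of other-cell lists and the tests of neighbouring genes and of the Il6ra region were chosen after the results they concern were seen; the GC tests were written after these patterns had been seen and before they were run. The offsets for GC content and length were added after the data had been seen.

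By the test of the difference itself, with camera at a preset correlation, the response to DSS differed between genotypes in 11 of 36 lists; 0 were called with an estimated correlation and 0 with fry. Knockout minus control, the median difference was 1.65 for absorptive colonocyte, 1.49 for ion and water transport, 1.70 for IL-6 and STAT3 response and 1.64 for immediate early genes. It was 0.75 for cholesterol synthesis, 0.88 for oxidative phosphorylation and 1.48 for non-polyadenylated histone genes. It was -0.41 for T cell, -0.41 for plasma cell, -2 for macrophage and monocyte and -0.72 for pan-leukocyte genes. Some of these hang on 1 library: oxidative phosphorylation was at 0.103 without knockout DSS replicate 11, and without replicate 12 ion transport was at 0.413 and absorptive colonocyte at 0.916. Across protein-coding genes, the difference of the DSS effect also followed GC content (r = 0.568).

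The lower epithelial genes in knockout mice on water enter several of these differences as their baseline. With GC and length trends taken out, the median log2 fold change over 97 genes of 4 epithelial lists was -1.86 (SE 0.21), against -1.86 (SE 0.26) before, so these trends do not account for the whole. SE values in this paragraph are over genes, which are not independent replicates, and do not measure the spread between libraries. A smaller epithelial share alone would raise markers of other cells alike, and the means of 11 lists of other cells differed (permutation p = 1e-04 with trends taken out, the smallest that 10000 draws can give, and 0.0064 as measured): red blood cell (2.23), macrophage (1.06), fibroblast (0.75), endothelial (0.73), glial (0.69) and B cell (0.23) genes were above 0, and plasma cell (-0.27), T cell (-0.3), regulatory T cell (-0.68), neutrophil (-0.87) and mast cell (-2.03) genes below. This replaced a first comparison of macrophage with fibroblast genes (difference 0.78, SE 0.58, and with trends taken out 0.31, SE 0.31). The permutation treats genes as independent and takes no account of variation in other cells between libraries. It therefore cannot exclude a smaller share, with the mix of other cells unchanged, as the whole cause. The lists furthest apart, red blood cell and mast cell, held 8 genes each. A smaller share, as the whole cause or part of it, stays open. So do an unrecorded library batch and the genotype, which cannot be told apart in this design.

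The GC trend of knockout against control on water was itself weighed. If it came only from the epithelial share, it would be absent within marker lists of other cells. Within the fibroblast, endothelial and macrophage lists, however, the correlation of fold change with GC content was -0.656 (95% interval -0.78 to -0.482, 62 genes). The interval treats genes as independent and does not measure the spread between libraries. Epithelium also expresses some genes of the other-cell lists, so the value speaks against the share as the only source without excluding it. A difference in RNA quality or library preparation between these libraries may be the source, and no label records either; processed pseudogenes took 1.33% and 1.3% of counts in the knockout and 0.65% to 0.77% in the control water libraries. Whether the genotype itself gives the trend cannot be told from batch in this design.

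Knockout DSS replicate 11 stood apart from replicates 10 and 12 in epithelial genes. With GC and length trends taken out, its median difference over the 4 epithelial lists was -3.25 (SE 0.27), against -3.24 (SE 0.28) before, so these trends do not account for it. The SE here is over genes and not between libraries. More severe injury or a preparation poor in epithelium could each give this, and 1 library cannot separate them.

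Other splits of the libraries were too few for a share under 0.05. For DSS against water in control mice the real split called 0 genes and the highest other 0, so all 10 of 10 splits gave as many. For knockout against control under DSS the real split called 6 and the highest other 0 (1 of 10 splits), and on water 5829 and 0 (1 of 10).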

How the results depend on the processing

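The GC and length offsets and the epithelial covariate were chosen after the data had been seen. No named gene reversed a call: of 3884 values of named genes under the alternatives, 3113 stayed the same, 446 became calls, 275 lost theirs and 50 changed sign without a call; of 3230 values of lists, 2619 stayed the same, 35 reversed, 262 lost their call, 150 became calls and 164 changed direction without a call. Genes changed in control mice under DSS (0) became 2 without a filter, 1019 with DESeq2, 10377 with limma voom, 2054 with only the groups compared, 12 with GC and length offsets and 713 with the epithelial covariate. In knockout mice under DSS (1) the count was 1867 with the leukocyte covariate, 571 with DESeq2, 1684 with limma voom, 0 with only the groups compared and 1038 with the epithelial covariate. For knockout against control under DSS (6) it was 3 with RLE, 7540 with the leukocyte covariate, 23 without a filter, 509 with DESeq2, 8302 with limma voom, 0 with only the groups compared, 58 with the offsets and 75 with the epithelial covariate. On water (5829) it was 9637 with the leukocyte covariate, 13732 with limma voom, 11910 with only the groups compared, 4010 with the offsets and 1219 with the epithelial covariate. For the difference of the DSS effect (0) it was 735 with DESeq2, 6724 with limma voom and 1 with the epithelial covariate. In the simulations, which gave all groups the same spread, DESeq2 made many false calls. The real groups differed in spread, so this need not carry over to the data. The cause of the other differences was not tested. Lists called were 25, 17, 18, 7 and 11 in the same order of comparisons, 1, 2, 0, 0 and 0 with an estimated correlation, and 16, 4, 3, 2 and 0 with fry. With the leukocyte covariate 10 lists were called in control mice under DSS and 10 for knockout against control under DSS, and with the offsets 16 on water. Of the 25, 17, 18, 7 and 11 list calls, the offsets kept 25, 16, 14, 6 and 10. The epithelial covariate kept 16, 14, 12, 3 and 7. The correlation of the DSS effects (0.004) was 0.462 with the leukocyte covariate. Leaving out each library in turn gave 0 to 954, 0 to 38, 0 to 6954, 0 to 9723 and 0 to 2 genes, 24 to 27, 14 to 20, 8 to 19, 6 to 10 and 7 to 18 lists, and correlations of -0.206 to 0.316; where 1 knockout water library remained, it was assumed to vary like the other groups. Depth of 20.3 to 50.2 in units of 1e6 counts was not the limit for the simulated 16-fold changes, which were mostly recovered except for the difference of the DSS effect; whether depth limits rare transcripts was not tested. Sex was not run as a covariate.

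With the leukocyte covariate the direction of the test turned for the lists that follow, in some without a change in the sign of the median. Called in the opposite direction were plasma cell (adjusted p = 0.0392), macrophage (0.0156) and immediate early (0.00453) genes in control mice under DSS, macrophage genes (0.0404) between genotypes under DSS and ion transport genes (0.00174) for the difference; the others were not called. The medians were then, in control mice under DSS, 0.70 for goblet cell, 0.95 for junction, 1.28 for ion transport, -0.55 for cytokine, -0.40 for T cell, -0.087 for regulatory T cell, -1.26 for plasma cell, -0.74 for macrophage, -1.61 for neutrophil, 1.39 for immediate early and 0.034 for pan-leukocyte genes. For knockout against control under DSS they were 0.49 for cytokine, 0.60 for cholesterol, 1.11 for T cell, 1.32 for plasma cell, 0.97 for macrophage, 0.26 for histone and -0.082 for pan-leukocyte genes, and for the difference -0.99 for absorptive colonocyte, -1.38 for ion transport, 0.37 for plasma cell, 0.27 for macrophage and -0.53 for immediate early genes. With the epithelial covariate the medians of lists turned in the same sense were 0.19 for antimicrobial and -0.45 for plasma cell genes in control mice under DSS, 0.078, 0.039 and 0.02 for absorptive colonocyte, junction and ion transport genes between genotypes under DSS, -0.027 and 0.016 for absorptive colonocyte and ion transport genes on water and 0.204 and 0.084 for the difference. Leaving out single libraries gave -1.09 to 0.38 for junction genes in knockout mice under DSS, and -1.426 to 0.058 for absorptive colonocyte and -1.25 to 0.02 for junction genes between genotypes under DSS. The epithelial covariate is the mean of the junction list, so its small values for junction and other epithelial lists were largely fixed in advance. The leukocyte covariate parts the control DSS libraries from all others, so values with it that involve this group are extrapolations. The cause of the turns was not tested further.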

Other observations

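The genotype fit over both treatments, and the tests of neighbouring genes and of the Il6ra region, were chosen after the data had been seen; the genes here were chosen after their values were seen.

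In a model with additive genotype and treatment effects (8 residual degrees of freedom), edgeR called 4401 genes between genotypes, 2760 higher and 1641 lower in knockout mice, with 9251 at an unadjusted p under 0.05. This model assumes the same genotype effect on water and under DSS. On water alone most calls went the other way (1896 higher and 3933 lower). The count was not tested with GC and length trends taken out or with libraries left out. By at least 2-fold, 38 genes parted every knockout library from every control library, 9 of them higher in knockout mice, among 978 that parted them at all. Pydc3 was at 5.37 to 33.1 CPM in knockout and 0.0647 to 0.432 in control libraries with a small prior count added. Apol10a, an apolipoprotein L gene, was at 0.847 to 2.68 CPM in knockout and 10.4 to 158 in control libraries, and its neighbours Apol7c and Apol7e on chromosome 15 were lower as well. Tnf, the inflammatory cytokine, was at 15 to 53.7 CPM in knockout and 126 to 236 in control libraries, and Cd74, the invariant chain of antigen presentation, at 198 to 608 and 1430 to 2070. With GC and length trends taken out, the gap between the nearest knockout and control libraries stayed for Tnf (-1.23 to -1.35 on the log2 scale) and shrank for Cd74 (-1.23 to -0.15). Cnr1, a cannabinoid receptor, was at 2.77 to 3.44 CPM in knockout and 0.209 to 0.739 in control libraries.

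Of these 38 genes, 81.6% still parted all libraries by any amount with GC and length trends taken out, and 23 (60.5%) by at least 2-fold, so the trends are not the whole cause but may account for part of the set. The count at 2-fold was added after the share by any amount had been seen. Strain variants at a few loci are a candidate explanation: with overlapping genes counted once, 14.3% of 35 genes had another within 500 kb, against a median of 5.3% and a 95th percentile of 10.5% in 10000 random sets (share at least as high 0.0275). Counted with overlapping genes, which share reads, the figure was 28.9%, and the overlaps were removed after that figure had been seen. By their coordinates, the genes so counted are Apol10a, Apol7c and Apol7e and a pair of predicted genes on chromosome 9. Without the Apol genes only that pair remains. Coregulation of the Apol genes, which lie in tandem, may give the same clustering. Near the deleted locus the number of these genes within 5 Mb of Il6ra was 1 (Bglap3) of 175 tested, 0.57% against 0.19% elsewhere (Fisher's exact p = 0.292), which cannot tell carried-along sequence from chance.

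Pydc3, Ifi202b and Mptx1 lie close together on chromosome 1 (173673675 to 173698392, 173962568 to 173982744 and 174330518 to 174332873). Ifi202b was at 112.7 and 34.33 CPM in knockout water replicates 7 and 8 and 42.14 and 41 CPM in knockout DSS replicates 10 and 12, at 0 in knockout DSS replicate 11, and at most 1.661 in control libraries. Mptx1 was at 10.55 and 90.63 CPM in knockout water replicates 7 and 8 and at most 0.2793 CPM in knockout mice under DSS.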
